A study of Homo sapiens with 30 samples.

How the data were processed

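RNA was measured by paired-end sequencing of total RNA from primary human endometrial epithelial cells and endometrial stromal fibroblasts. Cells from 3 endometrial donors were exposed for 5 hours to medium alone (mock), to a microvesicle fraction of seminal plasma, or to reconstituted seminal plasma, at a final concentration of 1% and after 3 washes. Each fraction was a pool from 15 men with acute HIV infection or from 15 uninfected men, so the 4 pooled fractions were each made once. This gives 5 groups of 3 libraries in each of 2 cell types, 30 libraries in all. The library names carry numbers, but nothing in the labels ties a number to a donor or a culture, so every p-value measures the spread between these libraries and not between men or between pools. One label field calls some samples acutely treated where the protocol describes men with acute infection. The protocol was followed.

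The authors aligned reads with TopHat2 version 2.1.0 and made 1 table per cell type with Partek, whose version is not given in the sources used here. The genome build and the annotation are not given in them either. The deposited values are a normalized signal: each value equals 0.0001 plus a number of fragments divided by the genomic span of the gene and multiplied by a constant, and every library of a table has the same total, 69056 for epithelial cells and 72552 for fibroblasts. This form was worked out from the values, since the labels do not define it. Because the tables were scaled separately, all tests were made within a cell type. Fragments were recovered from the signal. Of the values of 5 fragments or fewer, 95.4 to 96.9% in epithelial libraries and 93.7 to 97.9% in fibroblast libraries were whole numbers within 0.05, and recovered totals were 18.9 to 30.5 M and 15.4 to 42.5 M fragments. The signal divides by genomic span, introns included, so it compares a gene between libraries and not genes with each other. Coordinates are those of the tables, from which the build could not be read. Use of the strand is not stated, so antisense genes are uncertain, as are paralogs and pseudogenes such as the metallothionein genes and GK3P.

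Rows on alternate or unplaced sequences were set aside and tested separately. Rows on chromosome Y and those of XIST and TSIX were left out of the gene tests. Genes with a mean of at least 1 ppm (parts per M, M being mega) of a library's total signal were tested, 13000 in epithelial cells and 12182 in fibroblasts. Values were log2-transformed after adding 1, which is 14.5 ppm in the epithelial table and 13.8 in the fibroblast table, so log2 changes of weakly expressed genes are understated. Folds printed beside them are means over the 3 replicate numbers of the ratios of the signal without that addition, on a log scale, with the lowest and highest number in brackets, and no fold is given where a mock library held 3 fragments or fewer. The model was limma with a mean-variance trend on the group, over the 15 libraries of a cell type, with Benjamini-Hochberg adjustment and a threshold of 0.05. Means are in ppm of the library total with the SD, log2 changes have their SE, and n is 3 per group unless stated.

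Whether the numbers pair the libraries was checked before a block was used. After group means were removed, same-numbered libraries correlated across genes at 0.23 to 0.90 in epithelial cells and 0.48 to 0.88 in fibroblasts, over 30 pairs each, while pairs with other numbers reached at most 0.07 and 0.17. A fit with the replicate number as a block was therefore reported beside the fit on group alone, and is called the blocked fit. The 8 comparisons per cell type were each fraction with mock, infected with uninfected men for vesicles and for plasma, vesicles with plasma, and the difference between the 2 infection effects.

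The model, the filter, the threshold, the 32 gene lists of 488 genes, the alternatives in pseudocount, filter, TMM or quantile scaling, groups entering the fit, robust spread and block, the leaving out of each library, and the rule for naming genes were chosen before the data were examined. That rule takes, among genes past the threshold whose groups do not overlap and whose higher mean is at least 5 ppm, the 8 largest rises and the 8 largest falls. It adds from each list up to 4 genes past the threshold with the smallest p, or 2 members given as values where none passed, and always IL6, CXCL8, CXCL1, IL1B, PTGS2, CCL2, LIF and IL11. Genes were named from the fit on group alone where it called at least 20 genes, which held for fibroblasts given plasma, and otherwise from the blocked fit. For fibroblasts given plasma, the list part of the rule was also applied to the blocked fit, a step chosen after values were seen. Lists with at least 5 tested members, 28 in epithelial cells and 26 in fibroblasts, were tested with camera at its preset correlation of 0.01, and then with an estimated correlation and with fry.

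Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Count models, planned for the case that whole reads could be recovered, were not run, because the recovered values were not whole for every gene. limma-voom on recovered fragments, the gene-span trend of each library as a covariate, the leaving out of 3 fibroblast libraries that stand apart, and the block combined with the other alternatives were added after seeing the data. The blocked fits of gene counts without all libraries of 1 number were chosen before. On data simulated from the plasma comparison, with 5 runs of 200 changed genes, the fit on group alone recovered 56.6% of changes of log2 1 in epithelial cells and 53.8% in fibroblasts, and the blocked fit 87.9% and 88.1%. The changed genes were drawn only from those with a mock log2 value above log2 3, after the added 1. Changes were added on that log2 scale, so recovery was not measured for weaker genes, where it may be lower. False calls were 0.2 and 0.4% for the fit on group alone and 5.2 and 5.3% for the blocked fit, and no simulated gene was called in the wrong direction. The simulated noise was independent between genes and between libraries. The real libraries share structure, and some stand apart, so these rates need not hold for the real counts.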

Results

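Gene expression was measured in endometrial epithelial cells and endometrial stromal fibroblasts, the lining and the connective tissue of the uterus that semen can reach. Each cell type was given mock medium, microvesicles of seminal plasma, or reconstituted seminal plasma, pooled from men with acute HIV infection or from uninfected men, with 3 libraries per group. Recovered depth was 18.9 to 30.5 M fragments per epithelial library and 15.4 to 42.5 M per fibroblast library. Fibroblast libraries number 3 of the mock group and of both vesicle groups stood apart: the 10 highest genes held 22.9, 23.0 and 19.8% of their signal, against 14.8 to 17.0% in the other 12.

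Seminal plasma raised metallothionein genes in epithelial cells. These genes encode small cysteine-rich proteins that bind zinc and copper. MT1G rose from 21.6 ± 9.78 ppm in mock to 810 ± 380 with the plasma of uninfected men, a mean fold of 37.8 (31.5 to 43.6) and a log2 change of 4.46 ± 0.37 in the blocked fit (adjusted p = 0.00159, higher in 3 of 3 numbers). With the plasma of infected men MT1G reached 518 ± 439, a fold of 20.4 (16.1 to 32.1) and a log2 change of 3.60 ± 0.37 (adjusted p = 0.0136). The question of these comparisons was what whole plasma of either source does to the epithelium.

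**Figure D1:**
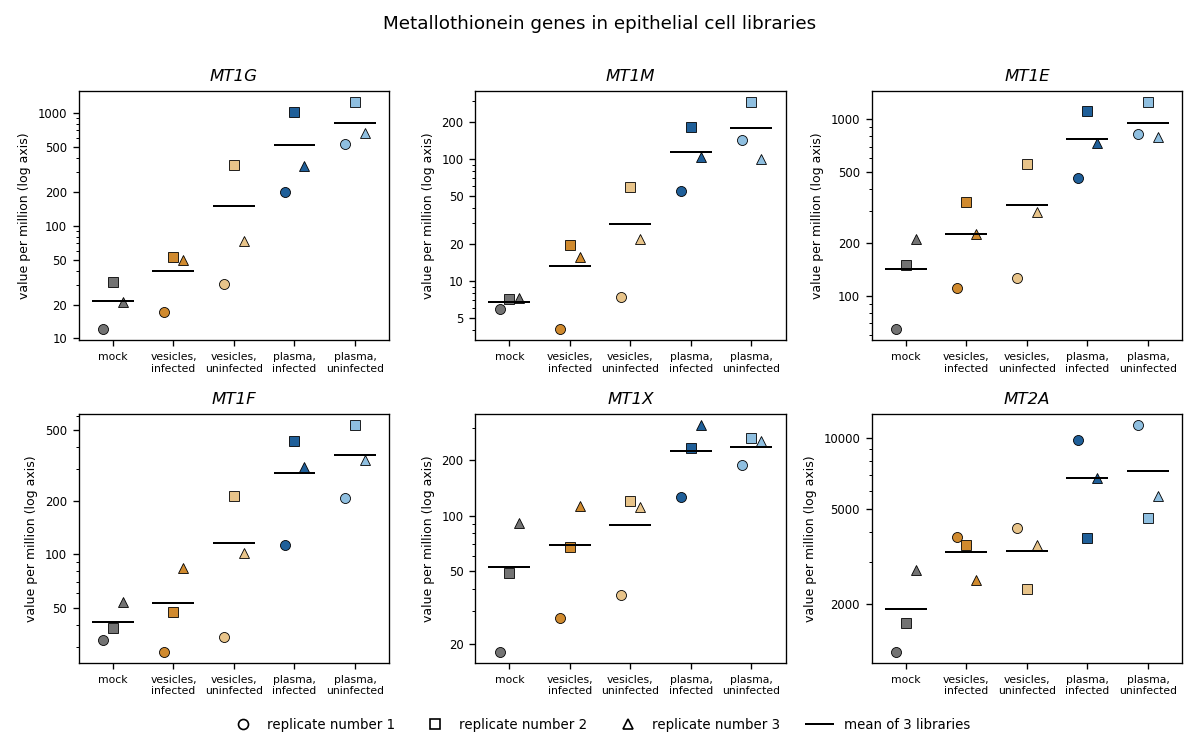
Signal in ppm of the library total, on a log axis, of 6 metallothionein genes in the 15 epithelial libraries. Marker shapes are replicate numbers and lines are means of 3 libraries, and MT1G in all 6 plasma libraries lies above the 3 mock libraries, whose mean is 21.6.

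All genes that passed in these plasma comparisons were metallothioneins of 1 cluster on chromosome 16. With the plasma of uninfected men, 7 of 13000 genes rose in the blocked fit and 0 fell. MT1M, at 56632622 to 56633986, rose 23.9-fold to 179 ± 101 (log2 3.06 ± 0.30, adjusted p = 0.00388), and MT1F, at 56657943 to 56659303, rose 8.19-fold to 359 ± 164 (2.65 ± 0.34, adjusted p = 0.0144). MT1E, at 56625673 to 56627113, already stood at 141 ± 72.7 in mock and reached 958 ± 253 (2.74 ± 0.28, adjusted p = 0.00388). MT1X, at 56682470 to 56684196, rose 5.41-fold (2.04 ± 0.21, adjusted p = 0.00388). MT1H and MT1A had few fragments in mock. MT1H, at 56669814 to 56671129, reached 110 ± 98.6 from 2.41 ± 1.91 (adjusted p = 0.00399), and MT1A, at 56638666 to 56640088, reached 10.5 ± 1.67 from 0.703 ± 0.377 (adjusted p = 0.00498). MT1G lies at 56666735 to 56668065 in the same cluster.

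With the plasma of infected men 5 genes rose and 0 fell in the blocked fit, and the 5 were among those 7. MT1M rose 15.0-fold (log2 2.46 ± 0.30, adjusted p = 0.0164), MT1E 5.73-fold (2.38 ± 0.28, adjusted p = 0.0156) and MT1X 4.87-fold (1.91 ± 0.21, adjusted p = 0.0152), and MT1H reached 71.4 ± 54.9 (adjusted p = 0.0239). MT2A, the most abundant metallothionein here, was 1258, 1661 and 2772 ppm in mock numbers 1, 2 and 3, 9779, 3789 and 6780 with the plasma of infected men, and 11350, 4618 and 5707 with that of uninfected men, and did not pass. On group alone limma called 0 genes for infected men and 1, MT1A, for uninfected men (adjusted p = 0.0309), with 232 and 110 genes at an unadjusted p under 0.05. limma-voom called 0 and 0 on group alone and 9 and 12 with the block. The 5 calls for infected men fell to 0 in the blocked fit without SP_Acut number 1, 2 or 3 or mock number 2, to 2 without mock number 1 and to 3 without mock number 3. For uninfected men the 7 calls were 5 to 9 without any 1 library. Without all libraries of number 1, 2 or 3 the blocked counts were 0, 3 and 1 for infected men and 0, 2 and 1 for uninfected men, and with the compared groups alone 1 and 1. For uninfected men the 1 call on group alone was lost without any 1 of the 6 libraries.

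The metallothionein and zinc list was the only list that held under camera, an estimated correlation and fry in the blocked fit of these 2 comparisons. Adjusted over the list alone, 9 members rose and 1 fell with the plasma of infected men, and 10 rose and 1 fell with that of uninfected men, with medians of 1.80 and 1.89. Its camera adjusted p was 2.25e-24 for uninfected men (adjusted p = 0.00995 with an estimated correlation) and 2.05e-21 for infected men (adjusted p = 0.0153 with an estimated correlation). The member that fell was SLC39A10, a zinc importer, by 0.22 ± 0.06 and 0.21 ± 0.06 on the log2 scale (0.00593 and 0.00834 adjusted over the list alone). SLC30A1, a zinc exporter that zinc induces, changed by 0.17 ± 0.34 and 0.66 ± 0.34 (0.622 and 0.0862 adjusted over the list alone).

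Amino-acid and endoplasmic reticulum stress genes were lower with plasma, short of the threshold over all genes. Adjusted over the list alone, 8 of 15 fell with the plasma of infected men and 5 with that of uninfected men. TRIB3, a stress kinase homolog, was 39.2 ± 12.8 and 37.0 ± 12.6 against 60.5 ± 10.3 in mock (adjusted p = 0.161 and 0.0882), and CHAC1, which degrades glutathione, was 89.0 ± 34.9 and 87.1 against 145 ± 33.7 (adjusted p = 0.483 and 0.661). Camera called the list at 8.59e-05 and 1.23e-07 (adjusted p = 0.312 and 0.371 with an estimated correlation, and 0.0309 for uninfected men on group alone). Of 27 interferon-response genes 6 fell with the plasma of infected men, adjusted over the list alone, with a median of −0.26 (camera 1.02e-05, adjusted p = 0.328 with an estimated correlation). OAS3, an antiviral nucleotide synthase, was 44.0 ± 15.9 against 66.1 ± 11.6 (adjusted p = 0.288) and OAS2 25.8 against 39.1 (adjusted p = 0.522). Immediate-early genes gave 3 rises adjusted over the list alone for infected men and 1 for uninfected men. EGR3 was 22.9 ± 1.69 against 15.4 ± 1.78 (adjusted p = 0.522), and the camera values of 2.07e-05 and 0.0013 became 0.272 and 0.387 with an estimated correlation.

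Inflammatory cytokine genes did not pass in epithelial cells given plasma. CXCL8, a neutrophil attractant, changed by log2 0.36 ± 0.27 with the plasma of infected men (adjusted p = 0.547), and IL6 by 0.78 ± 0.36 (adjusted p = 0.522). LIF, needed for implantation, changed by 0.36 ± 0.21 (adjusted p = 0.522), PTGS2, the inducible prostaglandin synthase, by 0.66 ± 0.75 (adjusted p = 0.664), CCL2 by 0.26 (adjusted p = 0.736), IL1B by 0.10 and CXCL1 by −0.06. IL11 was higher in plasma libraries of all 3 numbers, at 880, 63.3 and 229 with the plasma of infected men against 18.3, 8.19 and 157 in mock, and did not pass (adjusted p = 0.522). The widest gap was in number 1, where treated libraries also held more stromal-marker signal than mock, so a stromal source was not separated. CXCL5, another neutrophil attractant, was 568 ± 329 against 1195 ± 216 (log2 −1.18 ± 0.27, adjusted p = 0.483), and the list had 1 fall adjusted over the list alone and a camera adjusted p of 0.000657 (0.272 with an estimated correlation). CYR61, a target of mechanical signalling, was 1183 ± 52.5 against 1642 ± 69.7 (adjusted p = 0.483). ANKRD1, of the same list, was 10.9 ± 5.61 against 45.4 ± 31.7 (adjusted p = 0.522).

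In number 1, stromal markers were higher in treated epithelial libraries than in mock, and EPCAM and KRT8 were lower. COL1A1, a fibroblast collagen, was 907 ppm in mock number 1 against 4094 to 4570 in the treated libraries of that number, and 237 to 558 in every library of numbers 2 and 3. DCN was 281 against 649 to 874 and COL1A2 421 against 1201 to 1418 in number 1, while EPCAM was 509 against 251 to 343 and KRT8 463 against 290 to 369. The medians of the 14 stromal markers in the 4 treated groups were 1.35 to 1.73 in number 1, 0.06 to 0.57 in number 2 and −0.41 to 0.04 in number 3. Over all numbers they had medians of 0.53, 0.53, 0.47 and 0.61 for vesicles of infected and uninfected men and plasma of infected and uninfected men, and the 14 epithelial markers −0.16, −0.14, −0.24 and −0.25. Camera called the stromal list in all 4 comparisons (adjusted p = 0.423, 0.407, 0.328 and 0.387 with an estimated correlation) and the epithelial list likewise (adjusted p = 0.471, 0.44, 0.604 and 0.387 with an estimated correlation). Matrix-remodelling genes, which share COL1A1, COL1A2 and COL3A1 with the stromal list, had medians of 0.32, 0.31, 0.31 and 0.35 (adjusted p = 0.423, 0.407, 0.272 and 0.387 with an estimated correlation). Epithelial barrier genes had medians of −0.12, −0.13, −0.28 and −0.23 (adjusted p = 0.471, 0.44, 0.413 and 0.387 with an estimated correlation). MUC16, a surface mucin, was 80.3 ± 74.5 with the plasma of infected men against 138 ± 45.5.

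The remaining lists held no gene past the threshold over all genes in epithelial cells. Adjusted over the list alone, proliferation genes gave 4 rises with the plasma of uninfected men, cAMP and prostaglandin E2 targets 1 rise with each plasma, ERK feedback genes 1 rise and prostate and seminal vesicle genes 1 fall with that of uninfected men, and YAP and SRF targets 2 falls with that of infected men. Every camera call among these lists was lost with an estimated correlation (adjusted p = 0.387 for cAMP targets, for proliferation and for prostate genes with the plasma of uninfected men). Lists of TGF-beta targets, decidualization, hypoxia, glucocorticoid and progestin response and cholesterol synthesis had camera calls in at least 1 plasma comparison that were also lost (adjusted p = 0.363, 0.328, 0.272, 0.312 and 0.387 with an estimated correlation). NF-kB feedback, heat-shock, NRF2, LXR, p53, innate-sensor and endothelial lists gave no camera call and no member past either threshold in the blocked fit of any epithelial comparison. Lists of germ-cell, leukocyte, red-cell and platelet, and smooth-muscle markers had 1, 3, 0 and 3 tested members, too few to test.

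Vesicles changed no epithelial gene past the threshold. limma called 0 genes for vesicles of infected men and 0 for those of uninfected men, both on group alone and with the block, with 225 and 316 genes at an unadjusted p under 0.05 in the blocked fit, and limma-voom with the block called 1 and 1. MT1G was 149 ± 171 with vesicles of uninfected men against 21.6 ± 9.78 in mock (log2 1.67 ± 0.37, adjusted p = 1.0), a mean carried by number 2 at 345, while the other 5 vesicle libraries held 17.3 to 73.1. MT2A was 3294 ± 695 with vesicles of infected men against 1897 ± 784. Adjusted over the list alone, 5 metallothionein and zinc genes rose with vesicles of uninfected men (median 0.67, camera 3.17e-08, adjusted p = 0.253 with an estimated correlation, and 0.0411 on group alone). ANKRD1 was 7.84 ± 1.48 with vesicles of infected men (log2 −1.23 ± 0.31, adjusted p = 1.0) and CXCL5 674 ± 355. SPRY1, a feedback inhibitor of growth-factor signalling, was 95.7 ± 26.1 with vesicles of uninfected men against 63.3 ± 17.7, the 1 ERK feedback gene past the threshold adjusted over the list alone. Ciliated-cell markers had a median of −0.22 with vesicles of infected men (camera 0.00564, adjusted p = 0.471 with an estimated correlation), and HIV entry and restriction genes 0.07 with those of uninfected men (0.0156, adjusted p = 0.396 with an estimated correlation). Without MV_Neg number 3, 1 gene was called for vesicles of uninfected men in either fit.

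The direct comparison of vesicles with plasma placed the metallothionein genes lower with vesicles. This comparison asked whether the fraction mattered, over 6 libraries of each. The 7 genes called in the blocked fit were lower with vesicles. MT1G was 94.6 against 664 ppm, a ratio of 0.102 (log2 −2.92 ± 0.26, adjusted p = 0.00321), and MT1M 21.5 against 146, a ratio of 0.119 (−2.16, adjusted p = 0.00321). MT1X had a ratio of 0.310 (−1.47 ± 0.15, adjusted p = 0.00321), MT1H was 9.89 against 90.9 (adjusted p = 0.00321), and MT1E, MT1F and MT1A fell by 1.73, 1.87 and 0.51 on the log2 scale (adjusted p = 0.0058, 0.0152 and 0.00502). MT2A did not pass (adjusted p = 0.806). Adjusted over the list alone 10 zinc-list genes were lower and 1 higher (adjusted p = 0.00219 with an estimated correlation). Inflammatory cytokine genes had a median of −0.22 (camera 4.59e-08, adjusted p = 0.0645 with an estimated correlation, and 0.0252 on group alone), interferon genes 0.16 (4.67e-06, adjusted p = 0.593 with an estimated correlation), and 5 stress genes were higher with vesicles adjusted over the list alone (adjusted p = 0.238 with an estimated correlation). On group alone limma called 1 gene, MT1A (adjusted p = 0.0255), with 98 at an unadjusted p under 0.05, and limma-voom 0, or 6 lower with the block. That call was lost without MV_Acut number 1 or 3, SP_Acut number 1 or 2, or SP_Neg number 1 or 2, and 3 genes were called without MV_Neg number 2. The 7 blocked calls were 0, 4 and 2 without all libraries of number 1, 2 or 3.

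In fibroblasts, seminal plasma raised IL11 and lowered GDF15. IL11, a cytokine of the decidual response, at 55364382 to 55370463 on chromosome 19, rose from 35.4 ± 13.4 ppm to 872 ± 362 with the plasma of uninfected men, a fold of 24.3 (22.9 to 25.2) and a log2 change of 4.11 ± 0.48 (adjusted p = 0.0033). With the plasma of infected men it reached 738 ± 282, a fold of 20.9 (20.4 to 21.3, log2 3.90 ± 0.48, adjusted p = 0.00487). TNFRSF11B, the decoy receptor osteoprotegerin, at 118923557 to 118952144 on chromosome 8, rose 9.78-fold and 9.01-fold from 14.2 ± 2.21 (adjusted p = 0.000579 and 0.000981). GDF15, a stress cytokine, at 18386158 to 18389176 on chromosome 19, fell from 384 ± 64.0 to 107 ± 26.7 and 122 ± 30.2 (adjusted p = 0.0227 and 0.0474). GDF15 did not pass on group alone with the plasma of infected men when any 1 of the 6 libraries was left out, and in the blocked fit its adjusted p was 9.57e-05 and 0.000229.

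**Figure D2:**
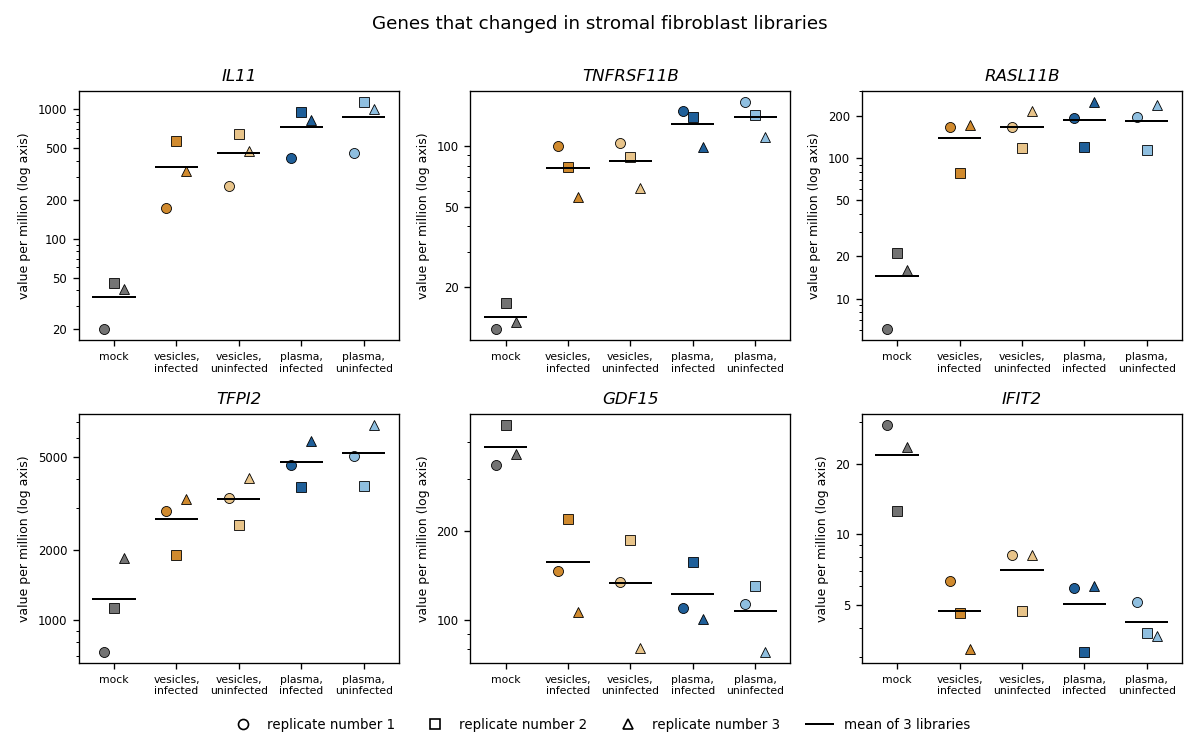
Signal in ppm of the library total, on a log axis, of IL11, TNFRSF11B, RASL11B, TFPI2, GDF15 and IFIT2 in the 15 fibroblast libraries. Marker shapes are replicate numbers and lines are means of 3 libraries, and the mean of IL11 is 35.4 in mock, 357 and 459 with vesicles and 738 and 872 with plasma of infected and uninfected men.

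The other large rises in fibroblasts given plasma, on group alone, joined signalling, clotting and hormone genes. RASL11B, a small GTPase, at 52862328 to 52866835 on chromosome 4, rose 14.2-fold with the plasma of infected men and 13.7-fold with that of uninfected men, from 14.4 ± 7.71 (log2 2.83 ± 0.36 and 2.78 ± 0.36, adjusted p = 0.00487 and 0.00448). TFPI2, an inhibitor of clotting proteases, rose 4.05-fold and 4.39-fold from 1231 ± 560 (adjusted p = 0.0209 and 0.0137). ADRA2C, an adrenergic receptor, rose 4.75-fold and 4.34-fold from 440.1 ± 193 (adjusted p = 0.0186 and 0.0227). TWIST2, a mesenchymal transcription factor, rose 4.91-fold and 4.88-fold from 26.0 ± 4.06 (adjusted p = 0.012 and 0.0113), and LXN, a protease inhibitor, rose 4.58-fold with the plasma of uninfected men (adjusted p = 0.0457). Hormone genes almost silent in mock came up. CGA, the shared subunit of chorionic gonadotropin, was 46.9 ± 17.1 and 54.5 ± 19.4 against 1.02 ± 0.809 (adjusted p = 0.00487 and 0.00357). SST, somatostatin, was 63.1 ± 28.5 and 68.0 ± 36.0 against 0.179 ± 0.165 (adjusted p = 0.0192 and 0.0147). CXCL2 was 6.22 ± 2.18 with the plasma of infected men against 1.08 ± 1.18 (adjusted p = 0.0453). Some of these calls were lost in many alternatives, with the direction kept. With the plasma of infected men these were TFPI2 (9 of 17), SST (11 of 17) and CXCL2 (10 of 16), and with that of uninfected men LXN (10 of 17).

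The falls on group alone included IL24, GADD45A, KLF2 and IFIT2. IL24, a cytokine, fell to 0.285 and 0.309 of mock with the plasma of infected and uninfected men (log2 −1.32 ± 0.19 and −1.25, adjusted p = 0.00934 and 0.0108). GADD45A, a DNA-damage response gene, fell from 445 ± 56.9 to 188 ± 14.8 and 183 ± 30.4 (adjusted p = 0.0109 and 0.00728), and KLF2, a transcription factor, from 41.1 ± 9.45 to 12.7 ± 2.80 and 14.1 ± 1.33 (adjusted p = 0.00487 and 0.00676). IFIT2, an antiviral RNA-binding protein, at 89301949 to 89309276 on chromosome 10, fell from 21.8 ± 8.49 to 5.04 ± 1.63 and 4.22 ± 0.807 (adjusted p = 0.0192 and 0.0126). CCNG1, a p53 target, fell to 0.641 and CXXC5 to 0.449 with the plasma of infected men (adjusted p = 0.0474 and 0.0138). CEMP1 fell to 0.432 and BBC3, a cell-death gene, to 0.258 with that of uninfected men (adjusted p = 0.0347 and 0.0434). The calls of CCNG1, CEMP1 and BBC3 were lost in 10, 10 and 9 of 17 alternatives, with the direction kept. The antisense gene C1QTNF9B-AS1, whose strand is uncertain, fell to 0.318 and 0.268 (adjusted p = 0.00487 and 0.00224).

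The number of fibroblast genes past the threshold depended on the block. On group alone 43 genes changed with the plasma of infected men, 33 higher and 10 lower, and 53 with that of uninfected men, 38 higher and 15 lower. With TMM scaling these were 73 higher and 68 lower, and 74 and 72. The blocked fit called 812 (527 higher, 285 lower) and 897 (576 higher, 321 lower). With the libraries of the compared groups alone the blocked fit called 5 and 4, all higher, and the fit on group alone 2 and 1. Under TMM scaling of the blocked fit the higher and lower genes were 637 and 659 for infected men and 674 and 698 for uninfected men, so that the excess of rises was not kept, and under quantile scaling 814 and 721, and 853 and 760. In the blocked fit 67 and 66 genes were called without all libraries of number 1. Without 1 library, the blocked counts for infected men were 454 (mock number 1), 365, 423 and 370 (SP_Acut numbers 1, 2 and 3), and for uninfected men 556 (mock number 1), 381, 521 and 339 (SP_Neg numbers 1, 2 and 3). On group alone they were 15, 18, 19 and 10, and 27, 23, 40 and 14 for the same libraries.

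Genes of decidualization, the change by which endometrial fibroblasts prepare for pregnancy, rose in fibroblasts given plasma. In the blocked fit 7 of 12 rose with the plasma of infected men and 8 with that of uninfected men, 0 fell, and 10 rose in each adjusted over the list alone. Camera adjusted p was 1.47e-06 and 4.84e-06 (adjusted p = 0.313 and 0.211 with an estimated correlation). FOXO1, a transcription factor of decidual cells, rose 2.96-fold and 3.02-fold (log2 0.94 ± 0.16 and 0.95, adjusted p = 0.00696 and 0.00573). CEBPB rose 1.73-fold to 1221 ± 189 with the plasma of infected men (adjusted p = 0.00137), BMP2 rose 1.91-fold with that of uninfected men (log2 0.80 ± 0.15, adjusted p = 0.0104), and IGFBP1 was 17.8 ± 12.8 against 2.21 ± 2.65 with that of infected men (adjusted p = 0.00697). On group alone 1 member passed in each comparison, SST.

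Hypoxia and glycolysis genes also rose in the blocked fit, 5 and 6 of 11, and 7 in each adjusted over the list alone. The other counts and gene values of this paragraph are of the blocked fit too. VEGFA, a vascular growth factor, rose 2.53-fold and 2.51-fold from 135 ± 44.0 (adjusted p = 0.00421 and 0.00384), and NDRG1 rose 2.19-fold with the plasma of infected men (adjusted p = 0.00153). The list's camera adjusted p was 0.00327 and 0.0052 (adjusted p = 0.453 and 0.45 with an estimated correlation). Cholesterol synthesis gave 1 and 5 rises of 17, and 7 and 9 adjusted over the list alone. INSIG1, a sterol sensor, rose 1.59-fold and 1.68-fold (adjusted p = 0.0134 and 0.00683). Camera called it at 0.00239 and 0.000579 (adjusted p = 0.557 and 0.488 with an estimated correlation). Of 12 cAMP and prostaglandin E2 targets 4 rose and 1 fell in each. NR4A2, a nuclear receptor, rose 5.30-fold and 5.45-fold (adjusted p = 0.00746 and 0.00663), RGS2 2.34-fold and 2.40-fold (adjusted p = 0.00308 and 0.00226) and CREM 2.80-fold with the plasma of infected men (adjusted p = 0.00105).

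In the blocked fit, immediate-early genes fell more often than they rose in fibroblasts given plasma. The counts were 7 against 1 with that of infected men and 7 against 2 with that of uninfected men. Counts and gene values of this paragraph are of that fit. On group alone JUN, CDKN1A and IFIT3 had adjusted p of 0.117, 0.552 and 0.512 with the plasma of infected men. JUN fell to 0.364 and 0.336 of mock (log2 −1.38 ± 0.17 and −1.48, adjusted p = 0.00102 and 0.000684), EGR3 from 36.9 ± 18.4 to 8.07 ± 2.91 and 8.08 ± 1.12 (adjusted p = 0.00275 and 0.00242), and KLF6 to 0.466 with the plasma of infected men (adjusted p = 0.00151). Camera called the list at 0.00239 and 0.00383 (adjusted p = 0.453 and 0.45 with an estimated correlation). Of 11 p53 targets 3 fell in each, GDF15, BBC3 and CDKN1A, the last from 351 ± 57.8 to 232 ± 81.0 and 218 ± 66.7 (adjusted p = 0.0145 and 0.00769), and camera called the list at 0.000149 and 0.000184 (adjusted p = 0.453 and 0.45 with an estimated correlation). Of 24 interferon genes 4 fell in each. IFIT3 fell to 0.363 and 0.349 (adjusted p = 0.000662 and 0.000456), XAF1 from 65.3 ± 25.6 to 35.0 ± 6.53 with the plasma of infected men (adjusted p = 0.013), and IFIT1 from 20.4 to 12.7 (adjusted p = 0.0113). Camera gave 0.0207 and 0.00058 (adjusted p = 0.557 and 0.45 with an estimated correlation).

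Cytokine genes of fibroblasts given plasma moved both ways. In the blocked fit 7 of 15 rose and 2 fell with the plasma of infected men, and 3 rose and 3 fell with that of uninfected men, or 11 and 3, and 7 and 4, adjusted over the list alone. IL33, an alarm cytokine, rose 16.8-fold and 18.3-fold from 2.36 ± 0.490 (adjusted p = 0.00169 and 0.00117). CCL2, a monocyte attractant, was 73.5 ± 63.7 and 71.9 ± 64.3 against 14.2 ± 11.7 (adjusted p = 0.0241 and 0.0266). PTGS2 was 29.1 ± 36.9 with the plasma of infected men against 5.54 ± 6.38 (adjusted p = 0.0371) and 23.3 ± 25.8 with that of uninfected men, which did not pass (adjusted p = 0.0586). CXCL1 was 13.2 ± 10.4 with the plasma of infected men against 1.49 ± 0.836 (adjusted p = 0.0255) and 2.69 ± 0.555 with that of uninfected men (adjusted p = 0.712). IL6 fell to 1.23 ± 0.662 and 0.613 ± 0.402 from 3.08 ± 1.72 (adjusted p = 0.0419 and 0.00971). CXCL8 was 135 ± 71.2 and 82.7 ± 39.1 against 48.2 ± 25.4 (adjusted p = 0.0796 and 0.311), LIF did not pass (adjusted p = 0.13 and 0.202), and IL1B was not tested. Camera called the list with the plasma of infected men alone (0.0207, adjusted p = 0.313 with an estimated correlation).

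Growth-factor, stress and metal genes of fibroblasts given plasma changed in smaller groups in the blocked fit, which gave the values of this paragraph. On group alone ID1 and ID3 had adjusted p of 0.63 and 0.354 with the plasma of infected men. Of 22 TGF-beta targets 2 rose in each, ID1 3.66-fold and ID3 3.99-fold with the plasma of infected men (adjusted p = 0.00524 and 0.00624). Among 17 ERK feedback genes 3 rose in each, and 2 and 1 fell. DUSP1, a MAP kinase phosphatase that the glucocorticoid list also holds, rose 2.46-fold and 2.58-fold (adjusted p = 0.00211 and 0.00144), and VGF 2.50-fold with the plasma of infected men (adjusted p = 0.00294). Of 15 stress genes 2 rose and 4 fell in each. DNAJB9, a chaperone of the endoplasmic reticulum, rose 1.65-fold (adjusted p = 0.00153) and HSPA5 1.42-fold with the plasma of infected men (adjusted p = 0.0135), while CHAC1 fell to 0.388 and 0.275 (adjusted p = 0.0188 and 0.00479) and TRIB3 to 0.392 with the plasma of infected men (adjusted p = 0.00858). Of 13 NRF2 targets 2 rose, HMOX1 4.63-fold and 5.30-fold (adjusted p = 0.0169 and 0.00998) and GCLM 1.89-fold and 2.09-fold (adjusted p = 0.00174 and 0.000692). Metallothionein and zinc genes gave 2 and 3 rises of 9. MT2A rose 2.08-fold and 2.22-fold from 2795 ± 1835 (adjusted p = 0.0237 and 0.0153), and SLC39A10 3.10-fold and 3.35-fold (adjusted p = 0.03 and 0.019). The MT2A call was lost in 11 of 21 alternatives with each plasma, with the direction kept. The MT2A gain in fragments per M, a mean over both pools, was 150, 308 and −42.5 in numbers 1, 2 and 3.

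In the other lists few genes passed in the blocked fit of fibroblasts given plasma, with that of infected and uninfected men in turn. NF-kB feedback gave 3 rises and 1 fall, then 1 rise and 3 falls, with NFKBIA, the inhibitor of NF-kB, up 1.5-fold with the plasma of infected men (adjusted p = 0.0243) and ICAM1 down with that of uninfected men (adjusted p = 0.0304). Glucocorticoid and progestin response gave 2 rises and 2 falls, then 2 and 1, with SGK1 up (adjusted p = 0.0211 and 0.00769) and ERRFI1 down (adjusted p = 0.00494 and 0.0097). Matrix remodelling gave 3 rises in each, among them ADAMTS1, a protease, 2.37-fold with the plasma of infected men (adjusted p = 0.0164). YAP and SRF targets gave 2 rises in each and 1 and 0 falls, with FHL2 up (adjusted p = 0.000933 and 0.000868), and LXR targets 1 rise, MYLIP (adjusted p = 0.0135 and 0.012). HIV entry and restriction gave 1 rise, SLFN11 (adjusted p = 0.0152 and 0.0141), and innate sensors 0 and 1, CD14 (adjusted p = 0.0157). Heat-shock genes gave 2 falls in each, HSPB1 to 0.504 with the plasma of infected men (adjusted p = 0.0057) and CRYAB (adjusted p = 0.0126). On group alone HSPB1 and CRYAB had adjusted p of 0.426 and 0.881 with that plasma. Proliferation gave 2 and 1 falls, with CCNE2 in both (adjusted p = 0.0241 and 0.0415).

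Some markers of other cells fell in the blocked fit of fibroblasts given plasma. KRT19 and KRT18, keratins of epithelial cells, fell, KRT19 to 0.486 from 1601 ± 1030.0 with the plasma of infected men (adjusted p = 0.00142) and KRT18 from 138 ± 6.5 to 86.6 ± 11.7 (adjusted p = 0.014). DES, of the smooth-muscle list, fell (log2 −0.58 and −0.63, adjusted p = 0.0165 and 0.0105). On group alone DES and KRT18 had adjusted p of 0.934 and 0.354 with the plasma of infected men. Stromal markers gave 1 and 2 rises, TWIST2 in both and PRRX1 with the plasma of uninfected men (adjusted p = 0.0382). Lists of ciliated, endothelial, red-cell and platelet, leukocyte, germ-cell and prostate genes had 3, 3, 0, 1, 1 and 3 tested members in fibroblasts.

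Vesicles changed many of these fibroblast genes in the same direction. IL11 rose 12.8-fold with vesicles of uninfected men (11.8 to 14.2, log2 3.21 ± 0.14, adjusted p = 8.31e-07) and 9.57-fold with those of infected men (8.13 to 12.6, log2 2.81 ± 0.14, adjusted p = 3.77e-06) in the blocked fit. RGS4, a regulator of G-protein signalling, fell from 152 ± 96.1 to 24.9 ± 18.7 with vesicles of infected men and to 22.2 ± 12.1 with those of uninfected men (adjusted p = 0.000658 and 0.00062). GDF15 fell to 0.395 and 0.332 of mock (adjusted p = 0.0022 and 0.00062). These comparisons asked whether the vesicle fraction by itself acts on the cells.

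**Figure D3:**
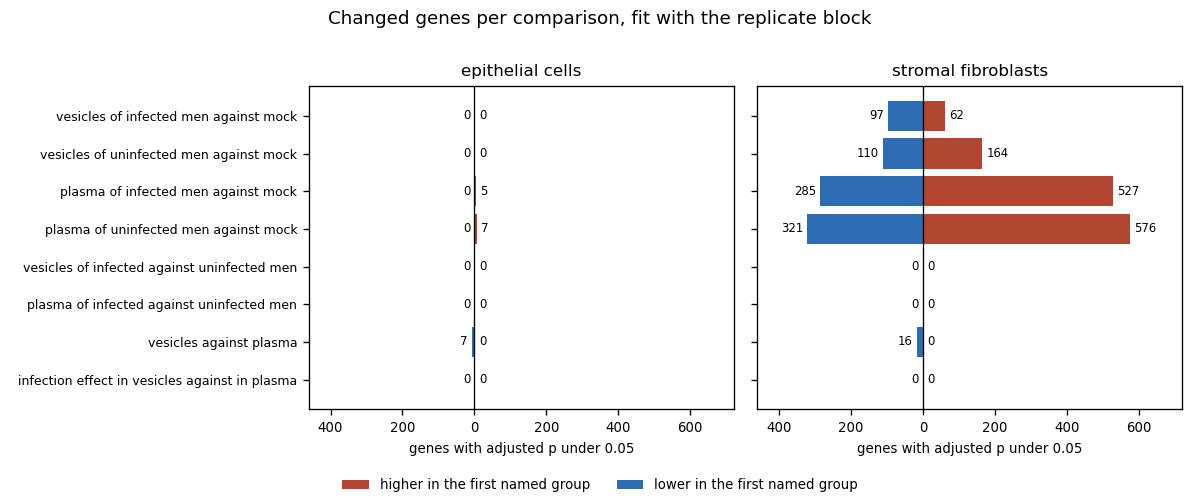
Number of genes higher and lower at an adjusted p under 0.05 in the blocked fit, by comparison, in epithelial cells and fibroblasts. Plasma compared with mock in fibroblasts gives the most, 812 and 897 genes, and each comparison of infected with uninfected men gives 0.

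Further rises with vesicles in fibroblasts were shared with plasma. TNFRSF11B rose 5.40-fold with vesicles of infected men and 5.89-fold with those of uninfected men (log2 1.69 ± 0.12 and 1.80, adjusted p = 7.99e-05 and 4.14e-05), RASL11B 10.3-fold and 12.7-fold (adjusted p = 0.00141 and 0.00062) and ADRA2C 3.90-fold and 4.13-fold (adjusted p = 0.00454 and 0.00261). FAM46A, of a family that adds poly(A) tails, rose 3.68-fold and 4.80-fold (adjusted p = 0.00523 and 0.00124), TWIST2 3.75-fold and 4.22-fold (adjusted p = 0.00329 and 0.00124) and RGS2 2.46-fold and 2.38-fold (adjusted p = 0.00789 and 0.0061). SST reached 56.3 ± 27.8 and 69 ± 47.2 (adjusted p = 0.000654 and 0.000311). TM4SF1, a surface protein, rose 8.41-fold (log2 2.44 ± 0.12, adjusted p = 9.5e-07) and NPTX1, a pentraxin, 9.02-fold (2.59 ± 0.40, adjusted p = 0.00741) with vesicles of uninfected men, and NPTX1 did not pass without MV_Neg number 3. Among the falls, JUN went to 0.384 and 0.418 (adjusted p = 0.00454 and 0.00488), IL24 to 0.327 and 0.319 (adjusted p = 0.00626 and 0.00412), PMAIP1, a cell-death gene, to 0.44 and 0.426 (adjusted p = 0.00789 and 0.00412) and EGR3 to 0.289 and 0.223 (adjusted p = 0.0162 and 0.00565). NR2F1 fell to 0.444 and FABP4, a fatty-acid carrier, to 0.383 with vesicles of uninfected men (adjusted p = 0.00201 and 0.0337), and KCTD12 to 0.504 with those of infected men (adjusted p = 0.0203).

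Counts of changed fibroblast genes with vesicles rested on the block as well. On group alone limma called 2 genes for vesicles of infected men and 7 for those of uninfected men, and the blocked fit 159 (62 higher, 97 lower) and 274 (164 higher, 110 lower). With the libraries of the compared groups alone these were 0 and 1 on group alone and 8 and 50 with the block. Without all libraries of number 1 the blocked fit called 5 and 12. Under TMM scaling the blocked counts for uninfected men were 260 higher and 313 lower, and under quantile scaling 324 and 340, so the excess of rises was not kept. The blocked counts for infected men were 66, 266 and 366 without mock number 1, 2 and 3, and 38, 56 and 55 without MV_Acut number 1, 2 and 3. Those for uninfected men were 126 and 428 without mock number 1 and 2, and 89, 91 and 63 without MV_Neg number 1, 2 and 3. On group alone the 2 genes were 0, 8 and 7 without mock number 1, 2 and 3 and 0 and 1 without MV_Acut number 1 and 3, and the 7 genes were 0 and 15 without mock number 1 and 2 and 0, 4 and 1 without MV_Neg number 1, 2 and 3.

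By list, vesicles of infected and uninfected men in turn gave 3 and 5 rises among 12 decidualization genes, or 7 and 9 adjusted over the list alone, with camera at 5.45e-10 and 1.27e-08 (adjusted p = 0.118 and 0.175 with an estimated correlation, and 0.0444 for infected men on group alone). IGFBP1, a secreted decidual marker, was 15.2 ± 11.9 and 18.8 ± 15.7 against 2.21 ± 2.65 (adjusted p = 0.0339 and 0.0128), CEBPB rose 1.63-fold and 1.64-fold (adjusted p = 0.00814 and 0.00497), and HAND2, a progesterone-regulated factor, 2.19-fold with vesicles of uninfected men (adjusted p = 0.014). Immediate-early genes gave 0 and 1 rises and 5 and 5 falls (camera 0.000705 and 0.000224, adjusted p = 0.484 and 0.423 with an estimated correlation). p53 targets gave 2 and 3 falls (adjusted p = 0.484 and 0.516 with an estimated correlation), and hypoxia genes 2 and 3 rises (adjusted p = 0.484 and 0.423 with an estimated correlation), with NDRG1 up 1.80-fold and 2.05-fold (adjusted p = 0.0239 and 0.00615). Cytokine genes gave 1 rise each, IL11, and 1 and 2 falls, and IL6 was 0.350 ± 0.219 with vesicles of uninfected men against 3.08 (adjusted p = 0.0124). Interferon genes gave 2 and 3 falls, IFIT2 to 0.222 and 0.332 (adjusted p = 0.00241 and 0.00488), and cAMP targets 1 and 4 rises, with NR4A2 up 4.81-fold with vesicles of uninfected men (adjusted p = 0.0252). Cholesterol genes gave 0 in each (adjusted p = 0.65 and 0.699 with an estimated correlation). TGF-beta targets gave 2 rises each, ERK feedback genes 2 each, and the stress list 1 rise, then 2 rises and 1 fall.

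The rest of the lists gave at most 2 changed fibroblast genes with vesicles. The glucocorticoid list gave 1 rise and 1 fall in each, DUSP1 (1.96-fold and 2.16-fold, adjusted p = 0.0278 and 0.0117) and ERRFI1, and the YAP and SRF list 1 rise each, FHL2 with vesicles of infected men (adjusted p = 0.00442). KRT19 fell in each, to 0.59 and 0.609 (adjusted p = 0.0219 and 0.0211), TWIST2 was the 1 stromal marker to rise, GCLM the 1 NRF2 target to rise (adjusted p = 0.0161) and HSPB1 the 1 heat-shock gene to fall (adjusted p = 0.0272) with vesicles of uninfected men. NF-kB feedback gave 0 changes with vesicles of infected men and 1 fall with those of uninfected men. The metallothionein, matrix, proliferation, LXR, HIV entry, innate-sensor, barrier and smooth-muscle lists gave 0 in both.

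The 16 fibroblast genes called between vesicles and plasma in the blocked fit were lower with vesicles, but the calls did not hold under every setting. IL11 was 408 against 805 ppm, a ratio of 0.492 (0.434 to 0.577, log2 −0.99 ± 0.10, adjusted p = 0.00694), and STC1, a secreted hormone, fell by 1.00 on the log2 scale (adjusted p = 0.0176). TMEM158 had a ratio of 0.601 (adjusted p = 0.0176), and PTGS1, TM4SF1, TNFRSF11B and CGA fell by 0.75, 0.66, 0.65 and 0.87 (adjusted p = 0.0176, 0.015, 0.0176 and 0.0111), as did the pseudogene GK3P by 0.48 (adjusted p = 0.015). STC1, PTGS1, TM4SF1, TNFRSF11B and CGA are named here after their values were seen. Under TMM scaling of the blocked fit 8 genes were called, 2 higher and 6 lower, with 5 of the 16 among them. Quantile scaling called 3 higher and 27 lower, with 11 of the 16 among them, and with the gene-span covariate 0 were called. limma called 0 genes on group alone (279 at an unadjusted p under 0.05) and 16 with the block, 8 of them with an adjusted p that rounds to 0.05, and limma-voom 0 and 8, of which 3 were higher and 5 lower. The 16 fell to 0 without MV_Neg number 1 or 3, 1 without SP_Acut number 3, 2 without SP_Acut 1, SP_Neg 1, MV_Neg 2 or SP_Neg 3, 3 without MV_Acut 2, 4 without SP_Acut 2, 6 without MV_Acut 3 and 7 without SP_Neg 2, and on group alone 1 gene was called without MV_Acut 2. Cytokine genes gave 2 falls, and 7 adjusted over the list alone (camera 0.0173, adjusted p = 0.485 with an estimated correlation). CXCL8 was 32.6 against 109 and did not pass (adjusted p = 0.113), nor did PTGS2 at 15.0 against 26.2 (adjusted p = 0.246) or MT2A at 3712 against 5343 (adjusted p = 0.234).

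No gene passed between pools of infected and uninfected men with all libraries in the fit, in either cell type, and a few alternatives called 1 or 2. limma called 0 genes for vesicles and for plasma, on group alone and with the block, and limma-voom called 0 as well. In the blocked fit the genes at an unadjusted p under 0.05 numbered 137 for vesicles and 252 for plasma in epithelial cells and 216 and 83 in fibroblasts. For the difference between the infection effects of vesicles and of plasma, limma called 0 genes in both cell types and both fits, with 144 and 130 at an unadjusted p under 0.05 in the blocked fit, and limma-voom 0. These comparisons were the ones that asked about acute infection, and each rests on 1 pool per source. With the compared groups alone 1 gene was called for vesicles in epithelial cells, in either fit, and 1 for plasma in fibroblasts, on group alone, and the blocked fit with no filter called 1 for plasma in fibroblasts. Leaving out 1 library gave 1 call in a few of them: in epithelial cells for vesicles, and for the difference between the effects, without MV_Neg number 3, and in fibroblasts for the same 2 without MV_Acut number 2, in either fit.

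The largest listed differences by source did not pass. In epithelial cells given plasma, OAS3 was 44.0 ± 15.9 with infected and 67.9 ± 16.5 with uninfected men (log2 −0.51 ± 0.10, 95% interval −0.73 to −0.30, adjusted p = 0.907), and OAS2 changed by −0.48 ± 0.12 (adjusted p = 0.907). Interferon genes had a median of −0.26 there, with 2 falls adjusted over the list alone (camera 5.74e-08, adjusted p = 0.819 with an estimated correlation), and −0.13 with vesicles (6.86e-11, adjusted p = 0.318 with an estimated correlation). MT1G changed by −0.86 ± 0.37 with plasma (interval −1.67 to −0.04, adjusted p = 0.907) and by −1.12 ± 0.37 with vesicles (adjusted p = 1.0). Proliferation and metallothionein lists had camera calls with vesicles (4.77e-11 and 2.39e-05, adjusted p = 0.318 for each with an estimated correlation). In fibroblasts given plasma, NFKBIA was 202 ± 28.0 with infected and 138 ± 17.4 with uninfected men (log2 0.51 ± 0.12, interval 0.24 to 0.78, adjusted p = 1.0), and CXCL1 13.2 ± 10.4 against 2.69 ± 0.555 (interval 0.26 to 1.02 of the fitted log2 change, which the added 1 shrinks at this level). NF-kB feedback and cytokine lists each had 2 rises adjusted over the list alone (camera 2.03e-08 and 0.00133, adjusted p = 0.356 and 0.119 with an estimated correlation, and 0.0199 for the cytokine list on group alone). IL11 in fibroblasts changed by −0.41 ± 0.14 with vesicles (interval −0.72 to −0.10, adjusted p = 0.796) and by −0.22 ± 0.14 with plasma.

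Changes correlated weakly between the cell types, and with 0 to 7 epithelial genes called this does not show that responses differ. Log2 changes of the 11528 genes tested in both correlated at Pearson's r of 0.18 and 0.30 for vesicles of infected and uninfected men and 0.08 and 0.24 for plasma, with Spearman's rho of 0.08, 0.21, −0.09 and 0.22. These are correlations across genes, which are not independent replicates, and were 4 of 8 computed, the others being 0.06 and 0.05 for infection with vesicles and plasma, −0.17 for vesicles against plasma and −0.30 for the difference between infection effects. Leaving out all libraries of 1 number moved r for plasma of infected men between −0.22 and 0.28. Within fibroblasts, 439 genes rose and 240 fell in the blocked fit with both plasma pools, and 59 rose and 79 fell with both vesicle pools, against 24.9, 7.5, 0.8 and 0.9 if calls fell independently, which leaves the shared mock libraries out. No gene was called in opposite directions in those pairs.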

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

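All tests in this part were chosen only after the results were seen. Of 230 gene results that could be compared between the cell types, 16 moved one way in all 3 numbers of epithelial cells and the other way in all 3 of fibroblasts. Random epithelial signs would give 28.1, so the 16 are not more than chance gives, and 63 moved the same way in all 3 numbers of both. The difference itself was not tested, and the genes are listed only as values. Each value below is the epithelial log2 change minus that of fibroblasts.

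EGR3, an immediate-early transcription factor, differed under every fraction. With vesicles of infected men the difference was 1.27, from 0.24 (0.01 to 0.44) in epithelial cells and −1.03 (−1.41 to −0.44) in fibroblasts. It was 1.34 with vesicles of uninfected men, 1.47 with plasma of infected men and 1.40 with plasma of uninfected men. IER2, another immediate-early gene, differed by 0.66 with vesicles of infected men (0.12 and −0.54). IGFBP1, a decidual marker, went the other way, by −1.12 with vesicles (−0.33 and 0.79) and −1.51 with plasma of infected men (−0.60 and 0.90). GADD45A differed by 1.35 with plasma of infected men (0.17 and −1.18). NFKBIE, an inhibitor of NF-kB, differed by 0.62 with vesicles and 0.72 with plasma of uninfected men.

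With plasma of uninfected men, IL24 differed by 1.94 (0.69 and −1.25), ICAM1 by 0.89 (0.35 and −0.54) and XAF1, an interferon-induced gene, by 0.84 (0.08 and −0.76). INSIG1 and IDI1, which belong to the sterol list, differed by −0.83 (−0.11 and 0.72) and −0.67 (−0.16 and 0.51). The zinc importer SLC39A10 also differed by −0.83 (−0.21 and 0.62).

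Genes on alternate sequences, which the comparisons leave out, held signal too. In the blocked fit for fibroblasts, 7 of 309 passed with plasma of infected men, 4 higher and 3 lower, and 6 with plasma of uninfected men, 4 higher and 2 lower, with 41 and 38 at an unadjusted p under 0.05. limma on group alone called 0 in both, with 19 and 19 at an unadjusted p under 0.05.

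The rise of metallothionein genes in epithelial cells given plasma was weighed first. Sharing of reads between paralogs would by itself leave the family's total unchanged. The summed fragments of 9 metallothionein rows, MT2A among them, rose in all 6 plasma libraries. The log2 ratio to the same-numbered mock was at least 1.44 (SD 0.74), which argues against sharing without any true rise. A rise of some members with their reads spread over the others would also raise the sum, so which MT1 genes rose is not settled. RNA carried over in the plasma would raise both cell types if it reached them in like amounts. The MT1 gain of fibroblasts was −3.61% of that of epithelial cells (−9.33 ± 27.8 and 259 ± 117 fragments per M, n = 3). Number 3, with a high mock value, made it negative, and numbers 1 and 2 gained 2.6 and 10.5 against 162 and 388, which argues against carry-over for the MT1 genes. For MT2A it stays open, as fibroblasts gained 33.9% of the epithelial gain (138 ± 175 and 407 ± 263), and 19.4% over all metallothioneins. A gain of short genes would move the 352 other genes of 932 to 1727 bases, whose medians were −0.01 with plasma of infected men and 0.02 with plasma of uninfected men, against 2.17 and 2.62 for the metallothioneins. With the gene-span covariate 1 of 5 calls stayed for infected men, at a median of 2.51 ± 0.33 from 2.38 ± 0.28, and 7 of 7 for uninfected men. Why the calls were lost was not tested. A response of the epithelial cells to plasma is left as a hypothesis for the MT1 genes as a family.

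The higher stromal markers in treated epithelial cultures were weighed second. In number 1 the 14 markers had medians of 1.35, 1.49, 1.53 and 1.73 over mock in the 4 treated groups. In number 2 they were 0.57, 0.06, 0.19 and 0.14, and in number 3 −0.41, 0.04, −0.29 and −0.03. Fewer stromal cells in the mock library of number 1 and a change with treatment in that number cannot be told apart, since number 1 has 1 mock library and the other numbers go both ways. The same markers changed by 0.33 ± 0.16 in fibroblast cultures, a mean and SD of 4 treated groups that share the mock libraries. That value is over all numbers, where the 4 medians were 0.12, 0.33, 0.49 and 0.39 in fibroblast cultures. In epithelial cultures they were 0.53, 0.53, 0.47 and 0.61 over all numbers. Fibroblast medians were not taken for number 1 alone, so a response of stromal cells to the fractions stays open. The design gives no other biological explanation that was tested.

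The many changed fibroblast genes were the last to be weighed. Fragment gain from short genes in some libraries is argued against as their whole cause with plasma of uninfected men, because 96.1% of the blocked calls stayed called with the gene-span covariate, which changed the count from 897 to 1485. The excess of rises over falls is another matter: with TMM scaling 49.1% of calls were higher. That scaling moved the median log2 change over all genes from 0.04 to −0.01, and could also even out a true excess. Composition of the libraries and a true excess of rises are therefore not told apart. For vesicles against plasma, the 16 genes had a median of −0.63 ± 0.08, and −0.54 ± 0.09 with the gene-span covariate, where 0 were called and the lowest adjusted p was 0.0593. The median change of these 16 genes moved little. The calls ended and the genes were picked from the same data, so the test does not decide on a gain of short genes.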

How the results depend on the processing

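The fits that join the replicate block to another alternative (other than gene counts and gene values without all libraries of 1 number, which were planned), limma-voom, the gene-span covariate and the leaving out of 3 fibroblast libraries (mock, MV_Acut and MV_Neg, number 3) were chosen only after the data were seen. The gene results carried through the alternatives numbered 252. Only results that passed in the fit that named them were carried, which leaves out the named genes that failed there and some others. Many were also chosen because their groups do not overlap, and the alternatives reuse the same libraries. A kept direction was therefore nearly given in advance and is no measure of stability. Of their 5173 alternative values 0 changed direction, 3626 kept their side of the threshold, 1547 lost it with the direction kept, and 5 results never lost it. Counts below need not be of the same genes. Count models were not run. Except where fewer libraries or genes enter a fit by construction, the cause of a change was not tested. When 1 library is left out of a group of 3, the others are assumed to vary like the remaining groups.

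In epithelial cells on group alone, the 1 call for plasma of uninfected men became 0 with a pseudocount of 0.1, with no filter, with a filter of 5 ppm, with TMM or quantile scaling and with limma-voom, 2 others with the groups of the comparison alone and 7 with the replicate block. The 1 call for vesicles against plasma became 0 with a pseudocount of 0.1, no filter, the filter of 5 ppm, the compared groups alone and limma-voom, and 7 with the block. The count for plasma of infected men went from 0 to 5 with the block. Within the blocked fit those 5 became 3 with a pseudocount of 5, 1 with the compared groups alone, 1 with the gene-span covariate and 9 with limma-voom. With no filter 0 of the 5 stayed and 1 other gene was called, lower. The 7 for plasma of uninfected men became 1 with the compared groups alone and 12 with limma-voom. Blocked limma-voom called 1 gene for each vesicle pool against mock. Vesicles of infected against uninfected men gave 1 with the compared groups alone, blocked or not.

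In fibroblasts on group alone, the 2 calls for vesicles of infected men became 6 and 1 with pseudocounts of 0.1 and 5, 5 with no filter, 7 with the filter of 5 ppm, 14 with TMM, 9 with quantile scaling, 0 with the compared groups alone, 9 with limma-voom, 4 without the 3 libraries and 159 with the block. The 7 for vesicles of uninfected men became 14 and 1 with the pseudocounts, 25 with TMM, 22 with quantile scaling, 1 other with the compared groups alone, 31 with limma-voom and 274 with the block. The 43 for plasma of infected men became 141 with TMM, 140 with quantile scaling, 2 with the compared groups alone, 120 with limma-voom, 118 without the 3 libraries and 812 with the block. The 53 for plasma of uninfected men became 146, 179, 1, 107, 137 and 897 under the same settings. Plasma of infected against uninfected men gave 1 with the compared groups alone, and 1 in the blocked fit with no filter. Vesicles against plasma went from 0 to 16 with the block.

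In the blocked fit for fibroblasts, TMM, quantile scaling, the compared groups alone, the gene-span covariate and the leaving out of the 3 libraries gave 393, 425, 8, 311 and 529 genes for vesicles of infected men, 573, 664, 50, 900 and 594 for vesicles of uninfected men, 1296, 1535, 5, 1698 and 1582 for plasma of infected men, and 1372, 1613, 4, 1485 and 1669 for plasma of uninfected men. limma-voom gave 405, 662 and 1239 for the first 3. For plasma of infected men TMM turned 527 higher and 285 lower into 637 and 659. TMM moved the share of higher genes for plasma of uninfected men from 64.2 to 49.1% and kept 753 of the 897 calls. The 16 for vesicles against plasma became 5 and 29 with pseudocounts of 0.1 and 5, 6 with no filter, 8 with TMM, 30 with quantile scaling (3 higher), 8 with limma-voom, 0 with the gene-span covariate and 4 without the 3 libraries.

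Leaving out 1 library or all libraries of 1 number gave these lowest and highest counts in epithelial cells, on group alone and then with the replicate block. Vesicles of infected men against mock gave 0 to 0 and 0 to 0, vesicles of uninfected men 0 to 1 and 0 to 2, plasma of infected men 0 to 0 and 0 to 3, and plasma of uninfected men 0 to 0 and 0 to 9. Infection gave 0 to 1 and 0 to 2 with vesicles and 0 to 0 and 0 to 1 with plasma, vesicles against plasma 0 to 3 and 0 to 7, and the difference between infection effects 0 to 1 and 0 to 2. In fibroblasts the ranges were 0 to 8 and 5 to 366 for vesicles of infected men, 0 to 15 and 12 to 428 for vesicles of uninfected men, 10 to 47 and 67 to 942 for plasma of infected men, and 14 to 57 and 66 to 927 for plasma of uninfected men. Infection gave 0 to 1 and 0 to 1 with vesicles and 0 to 0 and 0 to 2 with plasma, vesicles against plasma 0 to 1 and 0 to 18, and the difference between infection effects 0 to 1 and 0 to 1. The lowest blocked counts for fibroblasts against mock came without all libraries of number 1.

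Camera calls over all lists and comparisons numbered 58 in epithelial cells and became 6 with an estimated correlation and 3 with fry, and in the blocked fit 3 and 3 in place of 77. In fibroblasts 41 became 2 and 7, and in the blocked fit 0 and 22 in place of 41. Across genes, r between the cell types ranged, leaving out 1 number, over 0.10 to 0.16 for vesicles of infected men, 0.18 to 0.26 for vesicles of uninfected men, −0.22 to 0.28 for plasma of infected men and 0.14 to 0.24 for plasma of uninfected men. Signs changed for plasma of infected men (0.08 to −0.22 without number 1 and −0.09 without number 2), and without number 3 for infection with plasma (0.05 to −0.07), vesicles against plasma (−0.17 to 0.08) and the difference between infection effects (−0.30 to 0.11). In the simulation the fit on group alone recovered 9.7 and 4.7% of changes of log2 0.5 in epithelial cells and fibroblasts, so small changes are mostly missed without the block at this number of libraries.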

Other observations

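Both plasma pools changed fibroblast genes alike, with r of 0.94 across genes against 0.50 simulated for groups that share only the mock libraries, and both vesicle pools with r of 0.81. The covariance above that of the simulation was 0.0484 for the plasma pair and 0.0201 for the vesicle pair. In epithelial cells r was 0.80 for the plasma pair and 0.68 for the vesicle pair, with covariances above simulation of 0.0149 and 0.00268.

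Calls for vesicle and plasma of the same men overlapped in fibroblasts. Across genes r was 0.83 (rho 0.79) for uninfected and 0.69 (rho 0.50) for infected men, against a simulated r of 0.50. No rho was simulated, so the rho of infected men may be no higher than shared mock libraries give. The limits of the simulated r and covariance hold here too. The covariance above that of the simulation was 0.0329 and 0.0209. For uninfected men 153 genes rose and 104 fell with both fractions in the blocked fit, against 7.8 and 2.9 if calls fell independently, and for infected men 58 rose and 88 fell with both, against 2.7 and 2.3. IL11, TNFRSF11B, RASL11B and SST were among the largest rises with both. The 3 mock libraries are common to both and too few to split, so a part of each overlap from them is not excluded. The independent value leaves them out. Data simulated with no effect had an overlap of at most 0 in fibroblasts and 1 in epithelial cells, but such data give almost no calls, so the excess over either is not a measure of a shared effect.

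All tests of hypotheses and all splits in the blocked fit were chosen only after the results were seen, and the splits on group alone before. Zinc in the plasma is a candidate explanation for the metallothionein rise. It would also raise the exporter SLC30A1, which changed by 0.66 ± 0.34 with plasma of uninfected men (0.0862 adjusted over the list alone) and 0.17 ± 0.34 with plasma of infected men, and so the test does not decide. The fall of SLC39A10 in the same cells is the direction zinc would give. In fibroblasts MT2A passed in the blocked fit, but its gain in fragments per M was −42.5 in number 3, against 150 and 308 in numbers 1 and 2. SLC39A10 went the other way there with both plasma pools. With that of uninfected men it rose by log2 0.62 (0.32 to 1.07), so SLC39A10 does not decide either. A cAMP or prostaglandin response is a candidate explanation for the fibroblast changes, since CREM, NR4A2 and RGS2 rose, but the adjusted p of the target list with an estimated correlation was 0.488 with plasma of uninfected men, while fry gave 0.0105. It stays open.

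Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits on group alone and 4 within numbers, too few for a share under 0.05, so only counts are given. In epithelial cells the real count, the highest other and the number of splits as large were 0, 0 and 10 for vesicles of infected men, 0, 1 and 10 for vesicles of uninfected men, 0, 1 and 10 for plasma of infected men and 1, 3 and 2 for plasma of uninfected men. Within numbers they were 0, 0 and 4, then 0, 0 and 4, then 5, 3382 and 2, then 7, 0 and 1. The split with 3382 exchanges mock and plasma in number 2, far above the real count, which points to a structure of the samples other than their groups. Infection gave 0, 0 and 10 with vesicles and 0, 0 and 10 with plasma, and within numbers 0, 0 and 4 and 0, 1 and 4.

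In fibroblasts the same values on group alone were 2, 4420 and 2 for vesicles of infected men, 7, 0 and 1 for vesicles of uninfected men, 43, 0 and 1 for plasma of infected men and 53, 0 and 1 for plasma of uninfected men. The split with 4420 sets MV_Acut number 1 with mock numbers 1 and 2, against libraries that include number 3 of both groups, and points to the structure of the libraries that stand apart. Within numbers the values were 159, 0 and 1, 274, 0 and 1, 812, 0 and 1, and 897, 0 and 1. Infection gave 0, 0 and 10 for each fraction, and 0, 0 and 4 within numbers.

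For comparisons with 100 drawn splits a share can be given. Vesicles against plasma within numbers gave 7 genes in epithelial cells and 16 in fibroblasts, with 0 as the highest other in each. In both, 1 of 100 splits was as large, the real one, a share under 0.05. This speaks of chance division of single libraries and not of pools, since each of the 4 pooled fractions was made once. On group alone 5 of 100 splits gave as many as the 1 gene in epithelial cells, with 1590 as the highest other, so chance division is not excluded there, and the split with 1590 points to a structure of the libraries. In fibroblasts the real count was 0, which all 100 of 100 splits reach by construction, with 28 as the highest other, so this says nothing on chance. For the difference between infection effects, 0 genes were called, which all 100 of 100 splits reach by construction in both fits and cell types, with 1380 and 6 as the highest other in epithelial cells, on group alone and within numbers, and 1 and 1 in fibroblasts. The split with 1380 also points to a structure of the libraries.

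No library was a copy of another of its group: over the 30 pairs of libraries within a group, the chi-square per degree of freedom of recovered fragments was 63 to 382.2. Correlations of each library's deviations with gene span ran from −0.22 (SP_Acut number 3) to 0.15 (mock number 3) in epithelial cells and from −0.25 (MV_Neg number 1) to 0.16 (MV_Neg number 2) in fibroblasts.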
